A study of Bos taurus with 2 samples.

How the data were processed

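Gonads from 2 bovine fetuses, which the design text calls female, were profiled by droplet single-cell RNA sequencing from the 3' ends of transcripts at about day 50 of development. The labels give 1 library per fetus, replicate 1 with version 2 and replicate 2 with version 3 of the chemistry, so chemistry and fetus cannot be separated. Both libraries form a single group, and no gene was tested between them. Gene lists were ranked between the libraries against random lists, which takes no account of how fetuses vary. Tissue had been frozen, thawed and digested, and dead cells had been removed with magnetic beads before capture. Per the labels, 10000 cells were targeted for each library.

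The authors deposited raw counts, as unique molecular identifiers (UMIs) per gene and barcode, together with tables of gene identifiers with names and of barcode sequences, which hold no measurements (unit other). The submitters' processing notes name Cell Ranger 3.0.2 and Seurat 3.1.0.9003 and the genome build ARS-UCD1.2, without saying what each was used for. The gene annotation is not given in the sources used here. Barcodes had been filtered before deposit, and the lowest total in either library was 500 UMIs. Of 27607 gene rows, 17783 had a name of their own, 7087 had no name and 2737 shared a name. Genes are named here by the symbols that the files pair with Ensembl identifiers. No deposited cell annotation was used here.

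Replicate 1 held 3096 barcodes and 14454380 UMIs, with a median of 3286 UMIs and 672 genes. Replicate 2 held 16403 barcodes and 119161938 UMIs, with a median of 5843 UMIs and 1965 genes. Barcodes were kept with at least 500 genes and under 20% mitochondrial UMIs (13 mitochondrial genes). This removed 1288 barcodes for few genes and 58 for mitochondrial share in replicate 1, and 1255 and 308 in replicate 2. Doublets were called per fetus with Scrublet, as run by scanpy with exact neighbours, at an expected rate of 0.8% per 1000 barcodes. In replicate 1 the automatic threshold called 6 barcodes, so the 24 with the highest scores (1.37%) were removed up to the expected rate. In replicate 2 the automatic threshold removed 1063 (7.16%). This left 1726 cells with a median of 4712.5 UMIs and 13777 cells with a median of 5940.0 UMIs.

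Each fetus was clustered separately (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1). Before the data were examined, named genes were drawn into random sets of 8552 and 8553. The first set and the 124 cell type markers could enter clustering, and 9094 held-out genes, among them the gene lists and the germ stage markers, were kept out of it and alone were tested. Germ cells were then sub-clustered within each fetus on the first set and the germ stage markers. Clusters were named from cell type markers fixed before the data were examined. The rule that turns markers into a name was set after the data were first examined. A marker counted as raised at 2-fold or more over the library's other cells with a UMI in at least 10% of cells, and a name needed 3 raised markers. It was refused where another class had more markers among the cluster's top 10 genes by fold. Germ stage markers counted as germ cell markers. Without them no germ cell marker was among the top 10 genes of either germ cluster, which held 1 neural marker (STMN2) in each fetus and 1 epithelial marker (EPCAM) in replicate 1, so that neither cluster would have kept its name. The germ clusters raised 4 and 6 germ cell type markers and 7 stage markers each. NANOG, POU5F1, PRDM1, PDPN, SOX17, SOX15 and SYCP3 therefore helped to name the cells they are reported for, although they took no part in forming the clusters. Class names are this re-analysis's own and stand for cells that resemble the class.

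Raw counts, not corrected for free RNA, were summed per fetus and class, over classes with at least 20 cells in both fetuses. These were germ, endothelial, immune, surface epithelium and erythroid cells, which gave 10 sums. edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) was fitted with fetus as a block. It had 4 residual degrees of freedom, tested 5322 held-out genes and gave a common biological coefficient of variation of 20.6%. Each contrast was a class minus the mean of the other named classes on the log2 scale. P-values are two-sided and adjusted by Benjamini and Hochberg, with 0.05 as the threshold. They rest on how far class differences disagree between the 2 fetuses, pooled over the named classes, and not on cells as replicates. The overall difference between the fetuses is taken up by the block. Gene lists (22, fixed before the data were examined) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with the correlation estimated. Of 200 genes seeded in simulated data, 184 passed the low-count filter and were tested among 9151, and 136 were recovered. Of the tested ones, 88.4% of genes set at log2 -2, 40.0% at -1, 68.8% at 1 and 97.9% at 2 were recovered, and 8 of 144 calls were false. Apart from the seeded genes, the simulated classes and fetuses shared 1 mean profile. The real classes differ in many more genes, so these shares need not hold for them.

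A prior count of 2 enters the fold changes of a fetus taken alone, and edgeR's default prior count enters the fitted ones. For a gene with no UMIs in some class of both fetuses the fitted value depends on that prior. CPM (counts scaled to a fixed library total) are given in its place. CPM of a single library carry exact Poisson 95% intervals and shares carry exact binomial (Clopper-Pearson) 95% intervals. Both cover counting error only. A count of 0 is given the upper end of the same interval.

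The genes named in the text follow a rule fixed before the data were examined. In germ cells it takes the 10 largest positive and the 10 largest negative changes past the threshold with a mean log2 CPM of at least 4 and the same direction in both fetuses. It takes the 5 largest positive changes for each other class. For each list it takes up to 4 members past the threshold with the largest changes and up to 2 of highest expression that did not pass. It adds XIST, KIT, KITLG, CXCR4, CXCL12, CYP19A1, POU5F1, NANOG, STRA8 and SYCP3 whatever their result. The rule named 172 pairs of gene and class, and the report gives a value for 169 of them, while 3 are not reported here. Genes compared between the libraries, the X-linked genes with a Y-linked partner and the genes that mark mixed germ cells were chosen after their values or related values were seen.

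Alternatives fixed before the data were examined were DESeq2 1.42.0, no low-count filter, no fetus block, the other classes summed into 1, each fetus alone, doublets kept, 200 or 1000 genes per barcode, a mitochondrial limit of 10%, clustering on all variable genes or on the other random set of genes, both fetuses clustered together, resolutions of 0.5 and 2, and replicate 2 thinned to a median of 3286 UMIs. Leaving out erythroid cells, and leaving out mixed germ sub-clusters, were added after the data were seen. Between supporting and stromal cells no comparison was made, since neither class was named in replicate 1, and none between germ stages, since no later stage could be named. The planned comparison of X-linked with autosomal genes needs chromosome assignments for this build and was not run. XIST is not analysed here. Python 3.11.15, scanpy 1.11.5 and R 4.3.3 were used.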

Results

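The series asks which cell types make up the bovine fetal gonad. Gonads of 2 fetuses, each about 3 mm by 1 mm from fetuses of 4 cm crown to rump, gave 1 library each. After filtering, replicate 1 held 1726 cells with 10771381 UMIs and replicate 2 held 13777 cells with 101519430 UMIs. There is 1 library per fetus, so shares and CPM are given per fetus with intervals that cover counting error only.

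Germ cells made up 12.9% of kept cells in replicate 1 (223 cells, interval 11.4 to 14.6%) and 7.35% in replicate 2 (1012 cells, 6.92 to 7.79%). Endothelial cells made up 12.7% (11.2 to 14.4%) and 11.7% (11.2 to 12.3%). Immune cells were 15.8% (14.1 to 17.6%) in replicate 1 and 4.70% (4.36 to 5.07%) in replicate 2. Cells of the surface epithelium, the sheet that covers the gonad, were 5.21% (4.21 to 6.37%) and 10.9% (10.4 to 11.4%). Erythroid cells were 2.09% (1.46 to 2.88%) and 2.01% (1.78 to 2.26%). Stromal (21.4%, 20.8 to 22.1%), supporting (12.7%, 12.2 to 13.3%), steroidogenic (7.06%, 6.63 to 7.50%) and perivascular cells (1.28%, 1.10 to 1.49%) were named in replicate 2 alone. Their absence from replicate 1 can depend on the naming rule and need not mean a lack of such cells. Its cluster 6 (139 cells) raised 8 stromal markers and was refused the name, and other settings named up to 8.78% of its cells stromal, 4.69% perivascular and 4.46% steroidogenic. Supporting cells were named there only with both fetuses clustered together (0.290%). Of 11 supporting markers 10 were lower in that library than in replicate 2, so for this class the rule need not be the whole reason. In that fetus 51.3% (48.9 to 53.7%) stayed unnamed against 20.8% (20.2 to 21.5%) in replicate 2. Clusters with mesonephric or neural-crest-derived names were found in neither fetus, although 19.6% of replicate 1 took the latter name when the fetuses were clustered together. In replicate 2 the settings gave 9.09 to 31% for stromal, 3.77 to 15.7% for supporting and 5.94 to 15.9% for steroidogenic cells, far wider than the counting intervals. Dead-cell removal, the filter on genes per cell and the chemistry can all set these shares, and the erythroid share in replicate 1 was 11.7% with a minimum of 200 genes.

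**Figure D1:**
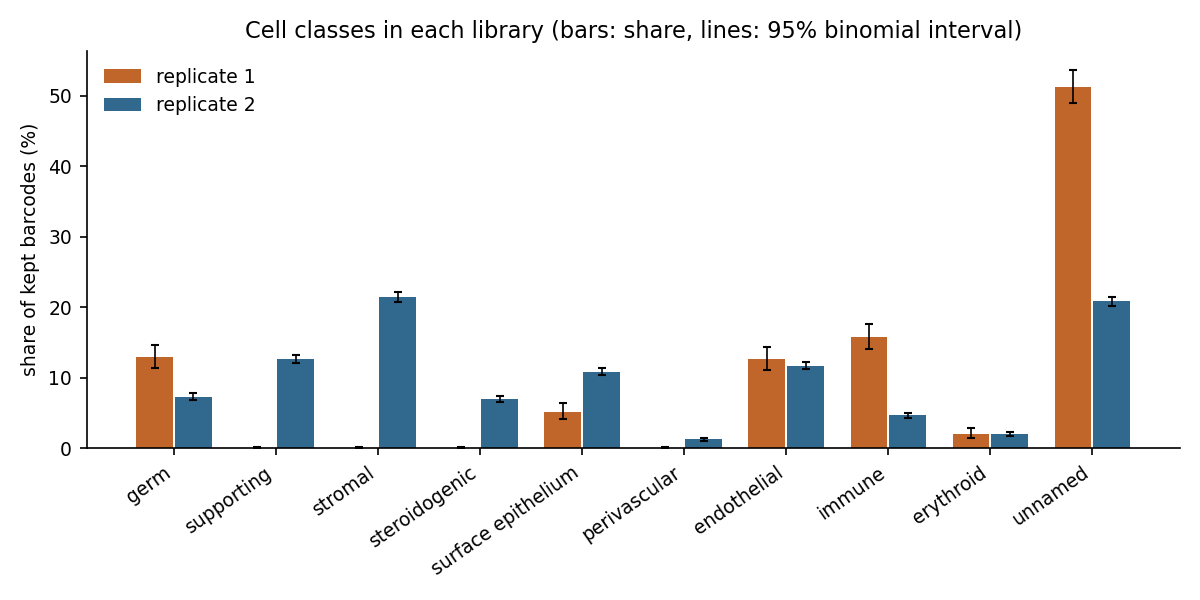
Share of kept cells (%, vertical axis) in each class (horizontal axis) for replicates 1 and 2, with lines for 95% binomial intervals. Germ cells are 12.9% and 7.35%, and the unnamed share is 51.3% in replicate 1 and 20.8% in replicate 2.

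The largest rises in germ cells included genes that also helped to name them. NANOG (ENSBTAG00000020916), a transcription factor of pluripotent cells, was higher by 6.89 on the log2 scale (SE 0.27, adjusted p = 1.8e-15), at 349.2 and 329.8 CPM in the germ cells of replicates 1 and 2 against a mean of 4.60 and 2.39 in the other classes. POU5F1 (ENSBTAG00000021111), which acts with it, was higher by 6.86 (SE 0.28, adjusted p = 2.4e-15). The transcription factor SOX15 was higher by 5.60 (SE 0.24), and SMC1B, a meiotic cohesin subunit, by 6.49 (SE 0.33). TUBA3E, a tubulin, was higher by 6.54, KLK8 by 5.83, MGARP by 5.59, ZNF296 by 5.43, HERC5 by 5.10 and TDRKH, a piRNA pathway protein, by 5.03. The largest falls were in genes expressed in somatic classes. LSP1 changed by -5.19 (SE 0.42, adjusted p = 4.2e-10), EHBP1L1 by -5.01, PTGS1 by -4.76, CCL14 by -4.66, CTSS, a lysosomal protease, by -4.59, S100A4 by -4.47, LGALS3 by -4.43, SULT1B1 by -4.37, TSPAN11 by -4.31 and CLIC1 by -4.28. Of 5322 genes tested, 1363 were higher and 1182 lower in germ cells, and 2478 of these calls had the same direction in both fetuses. Here and below, germ cells were set against endothelial, immune, surface epithelium and erythroid cells in the main setting. Stromal, supporting, steroidogenic, perivascular and unnamed cells took no part, so the calls do not describe germ cells against the whole gonadal soma. With erythroid cells left out, a choice made after the data were seen, 1267 and 1028 of them kept their call. Without fetus as a block the counts were 778 and 538. Of the calls 53.6% were higher, against 47.1% by DESeq2, which changes scaling and test together.

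Of 23 markers of later germ stages 22 were under 10 CPM in the germ cells of both fetuses (a bound set after the values were seen), 6 of them with 0 UMIs, and SYCP3 alone was above. The early markers SOX17, PDPN and PRDM1 helped to name these cells, so their level is no separate evidence of stage. SOX17, a determinant of early germ cell fate, reached 249.4 CPM (229.4 to 270.7) in replicate 1 and 431.3 CPM (420.1 to 442.8) in replicate 2, though endothelial cells also held it at 78.9 CPM (64.8 to 95.2) and 242.7 CPM (235.1 to 250.5). PDPN, a surface protein of early germ cells, reached 405.0 CPM (379.4 to 431.9) and 301.8 CPM (292.5 to 311.5), and PRDM1, a repressor of the somatic programme, 68.0 CPM (57.8 to 79.6) and 140.7 CPM (134.4 to 147.4). LIN28A, also an early marker, was low at 2.62 CPM (0.960 to 5.69) and 4.86 CPM (3.73 to 6.22). STRA8, which is induced by retinoic acid before meiosis, had 0 UMIs in replicate 1 (up to 1.61 CPM) and 6 UMIs in replicate 2 (0.463 CPM, 0.170 to 1.01). SYCP1, a synaptonemal complex protein, had 0 and 7 UMIs. The oocyte factors FIGLA (0 and 1 UMI) and LHX8 (0 and 0 UMIs) were at or near the limit of detection. SYCP3, another synaptonemal complex protein, was at 38.8 CPM (31.2 to 47.8) and 61.9 CPM (57.7 to 66.4), higher by 5.24 (SE 0.38, adjusted p = 5.8e-11) than in the other classes. Sub-cluster 3 of the germ cells of replicate 1 (47 cells) raised SYCP3 and DMC1, the only sub-cluster of either fetus to raise a stage marker over the other germ cells. Stage markers could enter the sub-clustering, so this rise is no separate evidence of a later stage. SYCP3 was at 70.9 CPM there, against 111.0 and 108.1 CPM in sub-clusters 1 and 2 of the germ cells of replicate 2. No cluster of later germ cells could be named, so early and later germ cells were not compared.

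**Figure D2:**
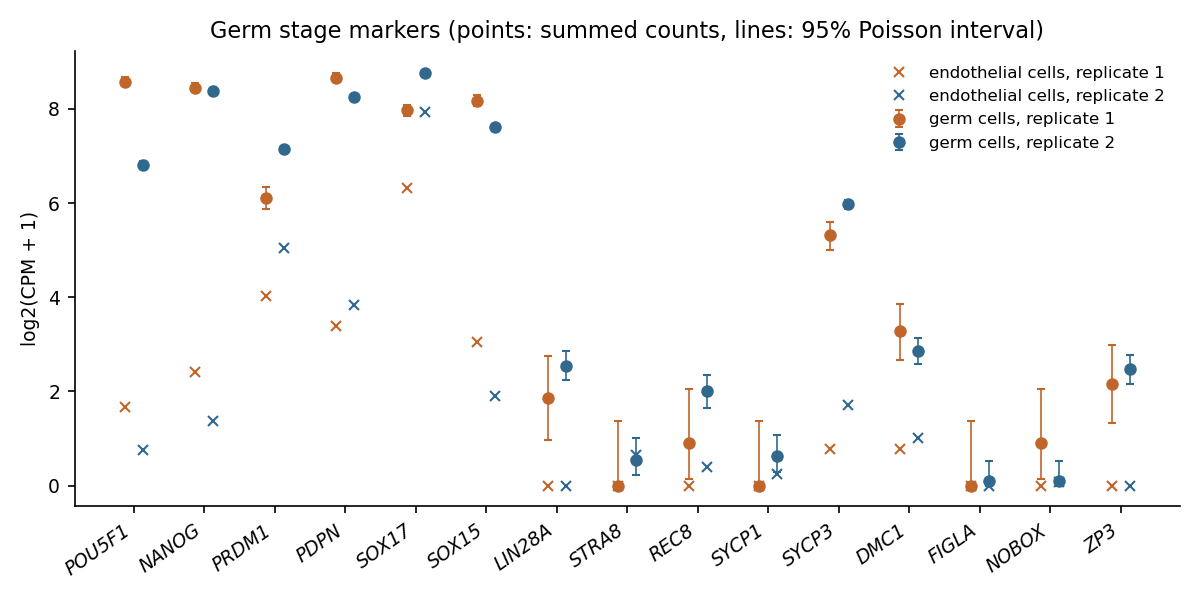
Expression of germ stage markers, as log2 of CPM plus 1 (vertical axis), per gene (horizontal axis) in germ cells (points with 95% Poisson intervals) and endothelial cells (crosses) of each replicate. SOX17 stands at 249.4 and 431.3 CPM in germ cells, while STRA8 has 0 and 6 UMIs.

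Genes for meiosis and for control of transposons were higher in germ cells. In the meiosis list 13 of 16 tested members were higher and 1 lower (camera adjusted p = 3.7e-05, and 0.438 with an estimated correlation). SPATA22 rose by 6.16 beside SMC1B. TERB1, which tethers chromosome ends to the nuclear envelope, stood at 10.0 and 24.5 CPM against a mean of 0 and 0.282, and TEX14 at 6.54 and 14.0 CPM against 0.218 and 0.143. TEX15 (-0.04, adjusted p = 0.976) and MSH5 (-0.99, adjusted p = 0.191) did not pass. In the piRNA list of 21 genes 5 of 6 tested members were higher (adjusted p = 0.00429, and 0.438 with an estimated correlation), with GTSF1 at 4.48, ASZ1 at 3.40 and HENMT1 at 2.55 beside TDRKH, and TDRD7 did not pass (-0.42, adjusted p = 0.525). In the pluripotency list 5 of 10 tested members were higher and none lower, and the list itself missed the threshold (adjusted p = 0.0543, and 0.438 with an estimated correlation). ALPL, an alkaline phosphatase, rose by 3.34 and LIN28B by 3.15, while ESRRB stood at 19.6 and 16.8 CPM against 0.218 and 0.0588, and TRIM71 at 5.23 and 11.6 CPM against 0.441 and 0.0841. KLF4 (-0.31, adjusted p = 0.575) and MYCN (-0.32, adjusted p = 0.415) did not pass. The low-count filter can let a gene in through germ cells alone, so tested members may lean towards genes high in them. Without the filter 20 of 30 meiosis genes (1 lower), 11 of 19 piRNA genes and 9 of 17 pluripotency genes were higher.

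Genes of respiration and DNA replication were also higher in germ cells. For oxidative phosphorylation 30 of 38 tested members were higher and none lower (adjusted p = 9.6e-10, and 0.438 with an estimated correlation). ATP5MC1 (1.67, SE 0.20) and ATP5F1A (1.45, SE 0.19), both of ATP synthase, NDUFS1 (1.66, SE 0.23) of complex I and UQCRC1 (1.41, SE 0.19) of complex III changed most, and UQCRH (0.34, adjusted p = 0.151) and COX7B (-0.06, adjusted p = 0.855) did not pass. Germ cells also held a higher mitochondrial share of UMIs, with medians of 5.67% and 5.67% against 2.36% and 3.08% in the other cells, and more UMIs per cell, 10544.0 and 11884.0 against 4198.0 and 5639.0. In the S phase list 20 of 25 members were higher and 1 lower (adjusted p = 1.1e-05, and 0.438 with an estimated correlation). MCM5 (2.5) and MCM4 (1.95) of the replicative helicase and GINS2 (2.44) rose, CCNE2 fell (-3.05), and USP1 (-0.52, adjusted p = 0.0558) and RRM2 (-0.32, adjusted p = 0.308) did not pass. In the list for G2 and M phase 15 of 30 members were higher (adjusted p = 1.8e-04, and 0.472 with an estimated correlation), among them the kinase AURKA (1.88), NDC80 (1.75), KIF2C (1.60) and cyclin CCNB1 (1.36), while CENPF (0.23, adjusted p = 0.394) and UBE2C (0.26, adjusted p = 0.366) did not pass. For glycolysis 6 of 19 members were higher and 3 lower, with PKM at 1.94, ENO1 at 1.65 and ALDOA at 1.63. The glucose transporter SLC2A1 was lower (-1.43), a call lost without erythroid cells (-0.26), and GAPDH (0.12, adjusted p = 0.669) and LDHB (0.38, adjusted p = 0.139) did not pass.

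Matrix and positional genes were lower in germ cells. Of 29 extracellular matrix genes 19 were lower and 1 higher (adjusted p = 6.2e-05, and 0.438 with an estimated correlation), led by POSTN (-3.48, SE 0.44), the collagens COL3A1 (-2.83, SE 0.38) and COL5A1 (-2.81, SE 0.34) and OGN (-2.81, SE 0.49). COL4A1 (-0.56, adjusted p = 0.13) and FN1 (0.27, adjusted p = 0.484) did not pass, and with the other classes summed FN1 was lower by that test (-2.19). Of 20 HOX genes 10 were lower and 2 higher (adjusted p = 0.00239, and 0.438 with an estimated correlation). HOXA9 (-4.82), HOXA6 (-4.22) and HOXD10 (-3.78) fell, and HOXA5 (0.09, adjusted p = 0.895) and HOXB7 (0.436 and 0.386 CPM against 5.87 and 8.21) did not pass.

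**Figure D3:**
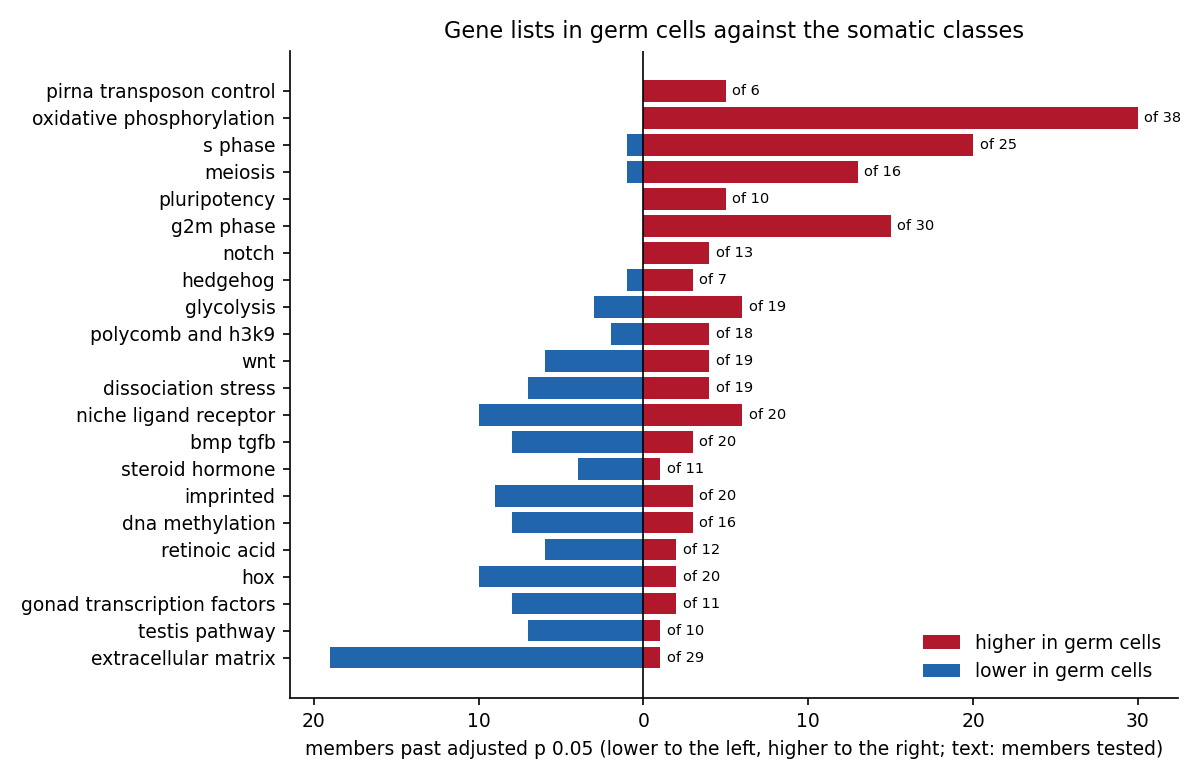
Number of members (horizontal axis) of each of 22 gene lists (vertical axis) that were higher (right) or lower (left) in germ cells at an adjusted p under 0.05, with the number tested beside each bar. Germ cells are set against the mean of endothelial, immune, surface epithelium and erythroid cells. Oxidative phosphorylation has 30 of 38 members higher and the extracellular matrix list 19 of 29 lower.

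The other lists did not pass camera in germ cells at the preset correlation (adjusted p from 0.0543 to 0.812), although single members did. With the correlation estimated, no list passed camera in germ cells (adjusted p from 0.438 to 0.871). Of 16 genes of DNA methylation 3 were higher and 8 lower: the demethylating enzyme TET1 rose by 2.84, GADD45B (-3.36), TET2 (-2.53) and GADD45G (-2.44) fell, and TRIM28 (0.57, adjusted p = 0.0595) and DNMT3A (-0.36, adjusted p = 0.255) did not pass. Of 20 imprinted genes 3 were higher and 9 lower, with falls in PLAGL1 (-3.82), the growth factor IGF2 (-3.31), NAP1L5 (-2.92) and MEST (-2.86), while PEG10 (-0.11, adjusted p = 0.737) and IGF2R (-0.55, adjusted p = 0.0866) did not pass. Of 18 genes for Polycomb and H3K9 methylation 4 were higher and 2 lower. CBX7 (3.63) and BMI1 (2.23) of Polycomb complexes rose and the H3K9 methyltransferases EHMT2 (-1.66) and SUV39H1 (-1.37) fell, while RING1 (0.11, adjusted p = 0.773) and SUZ12 (-0.26, adjusted p = 0.354) did not pass. Of 11 gonad transcription factors 2 were higher and 8 lower, with falls in ZFPM2 (-2.77), GATA6 (-2.61) and LHX9 (-2.58), which became -3.36, -4.14 and -4.03 without the mixed germ sub-clusters, an alternative added after the data were seen. RUNX1 stood at 3.92 and 4.32 CPM against 2.58 and 5.56, with 1 class at 0 UMIs in both fetuses, and lost its call without erythroid cells. Of 10 testis pathway genes 1 was higher and 7 lower: CITED1 stood at 19.6 and 21.6 CPM against 2.16 and 1.09, and CLDN11 (-2.63), PTGDS (-2.15) and NR4A1 (-1.67) fell. DMRT1 (0.36, adjusted p = 0.702) and HSD17B3 (-0.73, adjusted p = 0.495) did not pass. Without erythroid cells 5 of the 7 falls kept their call, and counts were not corrected for free RNA. Of 11 steroid hormone genes 1 was higher and 4 lower, with HSD17B1, which makes estradiol, at 4.26, the glucocorticoid receptor NR3C1 at -1.98, the lipoprotein receptor SCARB1 at -1.60 and POR at -0.64. HSD17B4 (0.07, adjusted p = 0.84) and FDXR (0.03, adjusted p = 0.952) did not pass, and POR lost its call without erythroid cells. Of 19 dissociation stress genes 4 were higher and 7 lower, with falls in BTG2 (-4.04), JUNB (-2.87) and FOSB (-2.12) and a rise in IER3 (2.14), while HSP90AA1 (0.46, adjusted p = 0.0679) and HSPA1A (0.53, adjusted p = 0.233) did not pass.

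Signalling genes went both ways in germ cells. KIT, the receptor for KITLG, was higher by 3.42 (SE 0.33, adjusted p = 1.1e-08) and the chemokine receptor CXCR4 was lower by -2.22 (SE 0.33, adjusted p = 5.9e-06), while its ligand CXCL12 did not pass (0.54, adjusted p = 0.291). KITLG, a supporting cell marker used in clustering and therefore not tested, stood at 72.7 CPM (68.0 to 77.8) in supporting cells of replicate 2 and at 8.48 CPM (6.97 to 10.2) in its germ cells, or 4.54 CPM (3.38 to 5.97) without their mixed sub-cluster. It also helped to name supporting cluster 6, so its level in supporting cells is no separate evidence. CYP19A1, the aromatase, stood in replicate 2 at 158.2 CPM (146.7 to 170.5) in supporting cluster 14 (683 cells), 10.3 CPM (8.09 to 12.8) in supporting cluster 6 (1070 cells) and 63.2 CPM (57.6 to 69.3) in steroidogenic cells and at 1.08 CPM (0.590 to 1.81) in germ cells, or 0.445 CPM (0.145 to 1.04) without that sub-cluster. Of 20 niche ligands and receptors 6 were higher and 10 lower. GFRA1, a GDNF receptor, rose by 4.25 and N-cadherin (CDH2) by 3.97, IGF1 (-4.28) and connexin GJA1 (-3.84) fell, and PTN (-0.38, adjusted p = 0.268) and PDGFB (-0.45, adjusted p = 0.261) did not pass. Of 20 genes for BMP and TGF-beta 3 were higher and 8 lower, with BMP4 at 3.19, TGFB2 at -3.55, TGFBR2 at -3.12 and TGFBR3 at -2.90, while ID1 (0.30, adjusted p = 0.599) and ID3 (-0.55, adjusted p = 0.342) did not pass. Of 12 retinoic acid genes 2 were higher and 6 lower: the binding protein CRABP2 rose by 2.74, and CRABP1 (-3.52), STRA6 (-2.5) and the synthetic enzyme ALDH1A2 (-2.07) fell, while RARA (-0.05, adjusted p = 0.924) and RXRB (0.59, adjusted p = 0.13) did not pass. Of 19 Wnt genes 4 were higher and 6 lower, with RNF43 at 3.34, LEF1 at -2.45, FZD2 at -2.13 and ZNRF3 at -2.07, and TCF7L2 (0.10, adjusted p = 0.959) and NKD1 (-0.78, adjusted p = 0.102) did not pass. In the hedgehog list 3 of 7 members were higher and 1 lower, with HHIP at 3.6, GLI3 at 1.67 and SMO at -1.14, a call lost without erythroid cells, and BOC (-1.13, adjusted p = 0.0539) and PTCH1 (0.02, adjusted p = 0.983) did not pass. In the Notch list 4 of 13 members were higher, with DLL3 at 3.56. LFNG (1.11, and -0.0051 to 2.41 in a fetus taken alone) and RBPJ (0.61) lost their calls without erythroid cells. HEY1, the remaining call, stood at 6.54 and 5.55 CPM against 5.43 and 7.05 and changed sign with the other classes summed. HES1 (-0.63, adjusted p = 0.145) and MFNG (1.31 and 0.308 CPM against 35.4 and 19.8) did not pass. Median and mean of this list were above 0 (0.53 and 0.46) and camera's direction was down, as it was for the steroid hormone list (0.028 and 0.11).

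Adjusted over the list alone, the counts in germ cells were as given above for 14 lists. They were 4 higher for DNA methylation and for imprinted genes, 2 higher for Notch, 2 lower for hedgehog and for S phase, 16 higher for G2 and M phase, 20 lower for the extracellular matrix and 7 higher for glycolysis.

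Each somatic class was compared with the mean of the other named classes. Across settings the genes higher and lower numbered 501 to 1126 and 135 to 1049 in endothelial cells, 649 to 1149 and 403 to 1163 in immune cells, 411 to 1198 and 185 to 1094 in surface epithelium, and 35 to 494 and 1 to 328 in erythroid cells. Endothelial cells had 954 genes higher and 534 lower. ECSCR, an endothelial surface protein, was higher by 7.49 (SE 0.26) and the peptide gene NTS by 7.41 (SE 0.25). LAMA4, a laminin chain, stood at 59.3 and 108.4 CPM against 0.218 and 0.731, APOLD1 at 86.8 and 135.3 CPM against 0.109 and 1.67, and the integrin ITGA5 at 164.3 and 127.7 CPM against 3.6 and 3.85. In these cells 10 of 13 Notch genes (1 lower, adjusted p = 5.1e-04, and 0.384 with an estimated correlation), 16 of 29 matrix genes (5 lower) and 10 of 20 HOX genes (none lower) (adjusted p = 0.00499 and 0.016, and 0.516 each with an estimated correlation) were higher. Their lists for meiosis (4 of 16 lower, 1 higher), G2 and M phase (4 of 30 lower) and oxidative phosphorylation (10 of 38 lower) were lower (adjusted p from 1.1e-05 to 0.00499, and 0.516 each with an estimated correlation). Immune cells had 1020 genes higher and 1003 lower. The complement factor gene CFD stood at 791.0 and 702.6 CPM against 2.82 and 1.11, the chemokine CCL4 at 281.7 and 79.0 CPM against 0.803 and 0.0137, TMIGD3 at 310.5 and 177.0 CPM against 0.109 and 0.191, the costimulator CD86 at 135.2 and 107.3 CPM against 0.290 and 0.0588, and CD200R1L at 86.3 and 98.5 CPM against 0.181 and 0.0858. Of 19 stress genes 15 were higher in them (adjusted p = 8.2e-09), and 23 of 29 matrix genes were lower (adjusted p = 3.4e-07), each with an adjusted p of 0.362 with an estimated correlation. Camera also placed lower in immune cells the lists for imprinted genes, Wnt, hedgehog, gonad transcription factors, G2 and M phase, oxidative phosphorylation and HOX (adjusted p from 0.0029 to 0.0263, and from 0.362 to 0.601 with an estimated correlation). Surface epithelium had 881 genes higher and 541 lower. The retinol carrier RBP4 was higher by 5.97 (SE 0.32), the keratin KRT15 by 5.56 (SE 0.29), PCP4 by 5.49 (SE 0.29), and the gonad transcription factors LHX9 by 5.11 (SE 0.32) and EMX2 by 4.76 (SE 0.31). In surface epithelium 12 of 20 HOX genes, 17 of 29 matrix genes (2 lower, adjusted p = 7.1e-06 each), 12 of 19 Wnt genes and 7 of 11 gonad transcription factors (1 lower and adjusted p = 4.7e-04 in each) were higher, and 14 of 19 stress genes were lower (adjusted p = 7.8e-07), all with an adjusted p of 0.280 with an estimated correlation. The hedgehog (4 of 7) and retinoic acid (6 of 12, 1 lower) lists were also higher there (adjusted p = 0.0101 and 0.0292, and 0.280 and 0.497 with an estimated correlation), and oxidative phosphorylation was lower (9 of 38, adjusted p = 6.8e-04, and 0.595 with an estimated correlation). Erythroid cells had 419 genes higher and 186 lower, which fell to 35 and 1 with at least 1000 genes per barcode and to 207 and 23 without fetus as a block. LY6G6D was higher by 10.12 (SE 0.33), TRIM10 by 9.32 (SE 0.30), the transcription factor NFE2 by 8.22 (SE 0.33) and the globin HBQ1 by 7.41 (SE 0.31), and ARG1 stood at 65.7 and 116.2 CPM against 0.508 and 0.479. By camera the S phase list was lower (5 of 25 lower, 1 higher) in erythroid cells. The lists for imprinted genes (6 of 20 higher), gonad transcription factors (6 of 11), the testis pathway (3 of 10), the extracellular matrix (12 of 29, 1 lower) and HOX (1 of 20) were higher by camera. For all 6 the adjusted p was from 7.3e-04 to 0.0112, and 0.480 each with an estimated correlation. The HOX list had a median of 0.98 and a mean of -0.192. The members behind the 5 higher lists include genes of gonadal somatic cells such as LHX9, AMH and COL1A2, and counts were not corrected for free RNA, so the calls do not establish expression by erythroid cells. AMH was at 647.3 CPM (543.8 to 764.7) in erythroid cells of replicate 1. Erythroid sums were the shallowest, at 213194 and 2460757 UMIs of which the median cell gave 70.9% and 76.2% to hemoglobin, and fold changes of the fetuses correlated across genes at 0.389, against 0.728 to 0.826 for the other classes (genes are not independent replicates).

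Many cells of replicate 1 that stayed unnamed expressed AMH, a hormone of supporting cells that regresses the Müllerian ducts in males. Over all kept cells AMH was at 3256 CPM (3222 to 3291) in replicate 1 and 0.640 CPM (0.494 to 0.816) in replicate 2. A UMI of AMH was found in 72.2% and 0.472% of cells, at median depths of 4712.5 and 5940.0 UMIs. In replicate 1 the share was 44.5% even in the larger immune cluster, where it may be background from free RNA, which was not tested. In 4 clusters of replicate 1, with 714 cells or 41.4% of those kept (39.0 to 43.7%), AMH reached 7335 to 9168 CPM (a grouping made after the values were seen), and elsewhere in that library it was at 60.6 to 647.3 CPM per cluster. Of these 4, clusters 7 (256 cells) and 8 (104 cells) had median mitochondrial shares of 0.25% and 0.244% and medians of 786 and 941.5 genes, while clusters 1 and 10 had 3.36% and 2.88%, with AMH at 8217 CPM (8059 to 8378) and 7335 CPM (7221 to 7450). No cluster of replicate 2 exceeded 3.72 CPM. Clusters 1 and 10 raised SOX10 and ERBB3, markers of neural-crest-derived cells, and SOX10 was at 12.7 CPM (10.7 to 15) in replicate 1 against 2 UMIs in replicate 2. SOX9 was low in both, at 0.743 CPM (0.321 to 1.46) in replicate 1 and 0.0394 CPM (0.0107 to 0.101) in replicate 2. HSD17B3, a testosterone-making enzyme, was at 74.2 CPM (69.1 to 79.5) against 0.266 CPM (0.175 to 0.387), DHH, a hedgehog ligand, at 55.5 CPM (51.2 to 60.2) against 5.04 CPM (4.62 to 5.50), and DMRT1 at 26.8 CPM (23.8 to 30.1) against 2.04 CPM (1.77 to 2.34). Genes higher in replicate 2 included RSPO1 (28.7 CPM, 27.7 to 29.8, against 3.25 CPM, 2.26 to 4.52). KITLG was at 22.1 CPM (21.2 to 23.0) there against 2.60 CPM (1.73 to 3.76). FST was at 14.7 CPM (14.0 to 15.5) against 2.32 CPM (1.5 to 3.43). CYP19A1 was at 15.8 CPM (15 to 16.6) against 1 UMI (up to 0.517 CPM). Also higher there were INSL3 (179.1 against 68.3 CPM) and the testis pathway genes FGF9 (18.1 against 10.1 CPM) and CLDN11 (12.4 against 6.96 CPM). Of 13 testis pathway genes 10 were higher in replicate 1 and 3 lower, whatever the size of the difference. Among them GDNF (1 UMI in replicate 1 and 4 in replicate 2) counts as higher and SOX8 (1 and 20 UMIs) as lower, both with overlapping intervals. These values were not tested, and fetus and chemistry differ together.

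**Figure D4:**
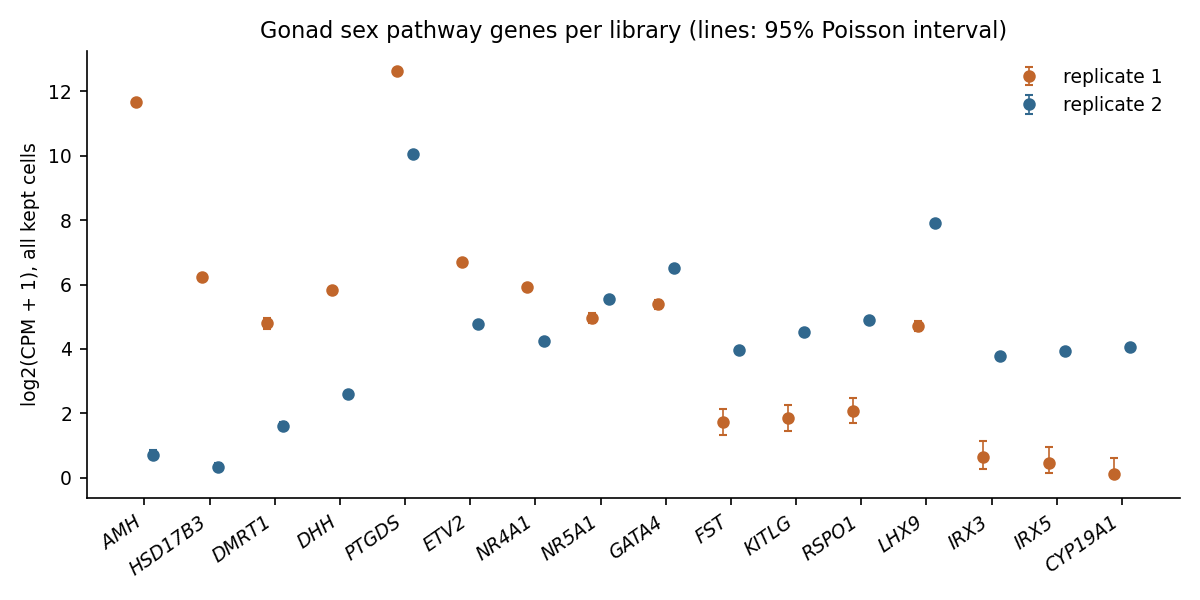
Expression of gonad sex pathway genes over all kept cells, as log2 of CPM plus 1 (vertical axis), per gene (horizontal axis) and replicate, with 95% Poisson intervals. AMH is at 3256 CPM in replicate 1 and 0.640 CPM in replicate 2, and RSPO1 at 3.25 and 28.7 CPM.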

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

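All tests of explanations in this part were chosen after the results they concern were seen. Of the barcodes with under 500 genes, which no comparison used, 862 in replicate 1 and 450 in replicate 2 gave over 20% of their UMIs to hemoglobin. Cluster 7 of replicate 1, which has no name and entered no test, held AMH at 9168 CPM.

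The testis pathway list stood higher in the library of replicate 1 than in that of replicate 2, by a median log2 ratio of 1.68 over 13 genes (10 higher and 3 lower), although the design text calls both fetuses female. A larger share of whole clusters seen in replicate 2 could not lift a gene above its highest cluster there. For 6 genes (AMH, HSD17B3, DHH, DMRT1, PTGDS and ETV2) the library of replicate 1 lay above that bound, which argues against this for them. A cluster's value is a mean over its cells, so a larger share of a minority inside a cluster cannot be judged by it. Of the other 7, FGF9, CLDN11 and SOX8 were lower in replicate 1 and hold no rise to explain, and for the rest it stays open. Cells of a kind missing from replicate 2 were not tested. The list stood at percentile 100 of 10000 random lists matched on expression, which argues only against a chemistry that shifts all genes of like expression. It was picked after its shift was seen, and chemistry and fetus differ together, so an effect of chemistry on these genes stays open. Within classes, without correction for free RNA, the list stood at percentile 100 in germ, endothelial and immune cells and 94.6 in surface epithelium. The supporting cell markers lay at the other end (percentile 0, median log2 ratio -1.54). A wrong sex label, or a male gonad, for replicate 1 would lower X-linked genes that have a Y-linked partner. The median of 11 such genes over the 4 non-erythroid classes stood at percentile 2.38, just inside the bound of 2.5 set after the data were seen. The classes alone gave 1.02 (germ), 4.14 (endothelial), 5.32 (surface epithelium) and 40.1 (immune). All 11 genes were lower in replicate 1 in the mean of these classes, in germ cells and over all kept cells (percentile 1.88). In endothelial cells and surface epithelium 10 were lower, and in immune cells 9. These shifts go the way this explanation predicts. The percentiles differ between classes and rest on 1 library per fetus, so this explanation stays open and unproven, and the label is kept as given. If it held, the libraries would differ in sex as well as in fetus and chemistry, and would not be replicates of 1 sex.

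Within germ cells, 26 cells of replicate 1 (11.7%) and 93 of replicate 2 (9.19%) formed sub-clusters led by genes of gonadal somatic cells, those of the unnamed AMH clusters in replicate 1 and those of supporting cells in replicate 2. In replicate 2 doublets are a candidate explanation, since these cells held 1.57 times the median UMIs and 14.2 times the doublet score of other germ cells, and a median hemoglobin share of 0.869 times theirs argues against free RNA of the suspension. In replicate 1 the median UMIs were 0.461 times those of other germ cells, which intact doublets would not give, but a median mitochondrial share of 9.16% against 5.65% leaves damaged cells, and so damaged doublets, open. Their hemoglobin share was 1.22 times that of other germ cells, which argues against free RNA of the suspension as the whole cause, so the origin of these cells stays open. No biological explanation was tested.

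Germ cells held a higher mitochondrial share than other cells in both fetuses. If damage were the whole cause, the germ cells with the most UMIs would hold no higher share. In the 25% of cells with the most UMIs the median share of germ cells was 1.77 times (replicate 2) and 2.12 times (replicate 1) that of the other cells, which argues against it. Within germ cells share and UMIs had rank correlations of -0.308 (replicate 1) and -0.108 (replicate 2), so damage may still add to the share of some cells. A larger respiratory programme remains a hypothesis, since 29 genes of oxidative phosphorylation were higher in germ cells when cells under 10% mitochondrial UMIs alone were kept, though this was found and tested on the same data.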

How the results depend on the processing

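Of 169 reported pairs of gene and class, 109 kept their direction in every alternative and their side of the threshold in each one with a test. A change of sign occurred for 30, of which 18 changed it in an alternative with a test and 27 in a fetus taken alone, and 2 of the 30 had passed. A call was lost in some alternative for 23. In alternatives with a test 2440 values of named genes kept direction and call, 90 changed sign, 62 lost and 53 gained a call. In a fetus taken alone 311 values kept their direction and 27 did not. Most calls were lost without the replicate block (19) and with at least 1000 genes per barcode (9). RBPJ lost its call in 10 alternatives, POR and RUNX1 in 9 each and LFNG in 7. For class shares 139 of 220 values stayed inside the interval of the main setting and 81 did not, and 112 of 158 counts of genes stayed within 1.5 times. Where camera was run, 261 list medians kept direction and call, 22 gained a call, 25 crossed 0 and none lost a call. The estimated correlation is not counted among these alternatives, and with it no list passed in germ cells. Where it was not, 78 kept their direction and 10 crossed 0. Changed values are grouped below, with fold changes and list medians in log2 for germ cells against the mean of the other classes. The cause of these changes was not tested. Leaving out erythroid cells and leaving out mixed germ sub-clusters were chosen after the data were seen. Each fetus alone gives fold changes without a test: LFNG ranged from -0.0051 to 2.41, and medians from -0.062 to 0.073 for Notch, -0.0020 to 0.41 for hedgehog, -0.25 to 0.060 for steroid hormone and -1.0 to 0.13 for dissociation stress genes. DESeq2 gave 2173 calls in germ cells, and 2075 of them were shared with edgeR in the same direction. All alternatives planned for the X chromosome, for supporting against stromal cells and for later against early germ cells were not run, because the comparisons were not made, although stromal or other classes were named in both fetuses in some alternatives. Camera was not run with DESeq2 or with the other classes summed. Depth limits genes near 0 CPM in replicate 1, where a class sum holds as few as 213194 UMIs.

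With at least 1000 genes per barcode, shares were endothelial 15.9%, germ 17.2%, surface epithelium 6.50% and unnamed 42.8% in replicate 1 and endothelial 12.7%, erythroid 1.26%, germ 8.25%, steroidogenic 10.3%, stromal 15.1%, supporting 11.4%, surface epithelium 12.1% and unnamed 22.9% in replicate 2. 591 genes were higher and 210 lower in endothelial cells, 35 higher and 1 lower in erythroid cells, 487 lower in immune cells and 475 higher and 325 lower in surface epithelium cells. PTCH1 (-0.14), HSD17B4 (-0.044), RRM2 (0.018), COX7B (0.15) and HOXA5 (-0.34) changed sign. Notch (-0.23), hedgehog (-0.14) and steroid hormone (-0.0040) medians crossed 0.

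With at least 200 genes per barcode, shares were endothelial 10.2%, erythroid 11.7%, germ 9.76%, stromal 8.78%, surface epithelium 3.92% and unnamed 39.1% in replicate 1 and endothelial 10.8%, erythroid 4.66%, steroidogenic 12.9%, stromal 27.3%, supporting 11.8% and unnamed 9.26% in replicate 2. 6 classes could be compared and 4 lists were lower in germ cells by camera. PTCH1 (-0.13), HSD17B4 (-0.014), FDXR (-0.11), HOXA5 (-0.32) and CXCL12 (-0.14) changed sign. Hedgehog (-0.12) and steroid hormone (-0.019) medians crossed 0. Pluripotency (1.49), imprinted (-0.51) and gonad transcription factor (-2.14) lists passed camera.

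Under a mitochondrial limit of 10%, shares were stromal 1.71% in replicate 1 and endothelial 12.3%, erythroid 3.50%, germ 7.94%, steroidogenic 5.94%, stromal 27.1%, supporting 4.49% and surface epithelium 11.6% in replicate 2. 315 genes were lower in endothelial cells, 214 higher and 19 lower in erythroid cells and 569 higher and 270 lower in surface epithelium cells. 6 classes could be compared and 4 lists were lower in germ cells by camera. PTCH1 (-0.15), HSD17B4 (-0.050), FDXR (-0.20), RRM2 (0.17), COX7B (0.11), HOXA5 (-0.31) and CXCL12 (-0.0046) changed sign. Notch (-0.079), hedgehog (-0.33) and steroid hormone (-0.20) medians crossed 0. Pluripotency (1.56), imprinted (-0.57) and gonad transcription factor (-2.54) lists passed camera.

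Keeping doublets, shares were immune 17.7% in replicate 1 and endothelial 12.7%, erythroid 2.28%, germ 8.47%, immune 5.27%, steroidogenic 7.92%, stromal 19.6%, supporting 3.77% and unnamed 27.2% in replicate 2. 75 genes were lower in erythroid cells. ID1 (-0.080), PTCH1 (-0.14), HSD17B4 (-0.043), FDXR (-0.027) and HOXA5 (-0.39) changed sign. Notch (-0.15), hedgehog (-0.14) and steroid hormone (-0.11) medians crossed 0. Testis pathway (-1.43) lists passed camera.

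Clustering on all variable genes, shares were perivascular 4.11%, steroidogenic 4.46% and unnamed 41.3% in replicate 1 and erythroid 3.07%, steroidogenic 15.9%, stromal 9.09%, supporting 10.1% and unnamed 25.4% in replicate 2. 259 genes were lower in endothelial cells, 243 higher and 33 lower in erythroid cells and 458 higher and 246 lower in surface epithelium cells. 7 classes could be compared and 4 lists were lower in germ cells by camera. PTCH1 (-0.081), HSD17B4 (-0.0076), FDXR (-0.066), PDGFB (0.19), RRM2 (0.14), COX7B (0.22), HOXA5 (-0.47) and CXCL12 (-0.40) changed sign. Notch (-0.091) and steroid hormone (-0.066) medians crossed 0. Imprinted (-0.73) and gonad transcription factor (-2.53) lists passed camera.

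Clustering on the other random set of genes, shares were stromal 7.88% and unnamed 41.7% in replicate 1 and erythroid 3.18%, steroidogenic 6.60%, stromal 16.7%, supporting 11.6% and unnamed 25.7% in replicate 2. 35 genes were lower in erythroid cells. 6 classes could be compared and 4 lists were lower in germ cells by camera. PTCH1 (-0.11), HSD17B4 (-0.0073), FDXR (-0.19), DMRT1 (-0.062), PDGFB (0.027), COX7B (0.027), HOXA5 (-0.53) and CXCL12 (-0.13) changed sign. Notch (-0.039), hedgehog (-0.11) and steroid hormone (-0.098) medians crossed 0. Pluripotency (1.78), imprinted (-0.61) and gonad transcription factor (-2.58) lists passed camera.

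Clustering both fetuses together, shares were neural-crest-derived 19.6%, perivascular 1.45%, steroidogenic 0.579%, stromal 5.74%, supporting 0.290% and unnamed 22.3% in replicate 1 and neural-crest-derived 0.131%, stromal 30.3%, supporting 15.7% and unnamed 8.22% in replicate 2. 305 genes were lower in endothelial cells, 52 lower in erythroid cells and 513 higher and 266 lower in surface epithelium cells. 7 classes could be compared and 4 lists were lower in germ cells by camera. HSD17B3 (0.26), PDGFB (0.23), COX7B (0.25), HOXA5 (-0.45) and CXCL12 (-0.55) changed sign. Pluripotency (1.98), imprinted (-0.81) and gonad transcription factor (-2.66) lists passed camera.

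At resolution 0.5, shares were erythroid 3.94% in replicate 1 and steroidogenic 9.28%, stromal 31%, supporting 13.9% and unnamed 7.48% in replicate 2. 265 genes were lower in endothelial cells, 227 higher and 41 lower in erythroid cells and 638 lower in immune cells. HSD17B4 (-0.063), COX7B (0.0027) and HOXA5 (-0.28) changed sign.

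At resolution 2, shares were perivascular 4.69% and unnamed 46.6% in replicate 1 and steroidogenic 11.1%, stromal 15%, supporting 9.23% and unnamed 26.8% in replicate 2. 123 genes were lower in erythroid cells. 6 classes could be compared and 4 lists were lower in germ cells by camera. PTCH1 (-0.14), FN1 (-0.079), COX7B (0.085), HOXA5 (-0.26) and CXCL12 (-0.14) changed sign. Notch (-0.029) medians crossed 0. Imprinted (-0.82) and gonad transcription factor (-2.44) lists passed camera.

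Thinning fetus 2, shares were erythroid 1.60%, germ 8.16%, steroidogenic 11% and supporting 6.95% in replicate 2. 257 genes were higher and 31 lower in erythroid cells. ID1 (-0.16), PTCH1 (-0.14), DMRT1 (-0.012), FN1 (-0.32) and HOXA5 (-0.38) changed sign. Notch (-0.61) and hedgehog (-0.14) medians crossed 0.

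By DESeq2, 104 genes were lower in erythroid cells. PTCH1 (-0.18), HSD17B4 (-0.016), FDXR (-0.028) and HOXA5 (-0.15) changed sign. Notch (-0.29), hedgehog (-0.18) and steroid hormone (-0.028) medians crossed 0.

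Without the low-count filter, 328 genes were lower in erythroid cells. TEX15 (0.018), RARA (0.0064) and COX7B (0.0011) changed sign. Notch (-0.14) and steroid hormone (-0.47) medians crossed 0. Pluripotency (1.60) lists passed camera.

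Without the replicate block, 501 genes were higher and 135 lower in endothelial cells, 207 higher and 23 lower in erythroid cells, 778 higher and 538 lower in germ cells, 649 higher and 403 lower in immune cells and 411 higher and 185 lower in surface epithelium cells. ID1 (-0.031), PTCH1 (-0.13), COX7B (0.015), HOXA5 (-0.027) and RING1 (-0.12) changed sign. Hedgehog (-0.13) medians crossed 0. Pluripotency (1.57) lists passed camera.

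Summing the other classes into 1 per fetus, 1049 genes were lower in endothelial cells, 268 higher in erythroid cells and 1094 lower in surface epithelium cells. TEX15 (0.12), ID1 (-1.42), TCF7L2 (-0.15), HEY1 (-0.85), PTCH1 (-0.062), HSD17B4 (-0.046), RRM2 (0.17), FN1 (-2.19), COX7B (0.25) and HOXA5 (-0.99) changed sign. Notch (-1.44), steroid hormone (-0.021) and glycolysis (-0.29) medians crossed 0.

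Without erythroid cells, 857 genes were lower in surface epithelium cells. TEX15 (0.53), PEG10 (0.065), TCF7L2 (-0.082), HSD17B4 (-0.081), HSD17B3 (0.37), RRM2 (0.18), FN1 (-0.23), COX7B (0.25) and HOXA5 (-0.077) changed sign. Notch (-0.47) and steroid hormone (-0.050) medians crossed 0.

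Leaving out the mixed germ sub-clusters, 5 lists were lower in germ cells by camera. TEX15 (0.0018), FDXR (-0.18) and DMRT1 (-0.18) changed sign. Steroid hormone (-0.051) medians crossed 0. Imprinted (-0.40), gonad transcription factor (-3.08) and testis pathway (-1.55) lists passed camera.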

Other observations

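Replicate 2 held the gonadal somatic classes that could not be named in replicate 1, and their sex pathway genes were measured there without a test. Aromatase (CYP19A1) differed between the supporting clusters, at 158.2 CPM (146.7 to 170.5) in cluster 14 and 10.3 CPM (8.09 to 12.8) in cluster 6, and was at 63.2 CPM (57.6 to 69.3) in steroidogenic cells, against 10.2 CPM (8.82 to 11.8) in stromal and 1.13 CPM (0.671 to 1.79) in endothelial cells. CXCL12, the ligand of CXCR4, was at 96.5 CPM (89.4 to 103.9) in steroidogenic cells and 79.6 CPM (75.5 to 83.8) in stromal cells of replicate 2, against 18.4 CPM (16.1 to 20.8) in its germ cells. KITLG was at 72.7 CPM (68.0 to 77.8) in supporting cells (90.0 CPM, 83.4 to 97.1, in cluster 6 and 43.2 CPM, 37.2 to 49.8, in cluster 14), 26.3 CPM (23.8 to 28.9) in endothelial and 18.5 CPM (16.6 to 20.6) in surface epithelium cells. Cluster 6 took its name from 3 raised markers, WNT6, KITLG and RSPO1, so a raised KITLG there was a condition of the name.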
